A study of Mus musculus with 8 samples.

How the data were processed

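The deposited files hold unfiltered matrices of UMI counts, 1 per library, for 8 libraries of viable CD45+ cells from treated tumours: 4 from RT with AAV-iLuc and 4 from RT with AAV-iIL12, 6 days after treatment. Per the submitters' processing notes, the authors made the counts with bcl2fastq 2.20.0 and Cell Ranger 7.0.0 against mm10; per the file headers the software was Cell Ranger 4. Whether intronic reads were counted, and which annotation was used, is not given in the sources used here. Values were whole numbers for 32285 genes, with no normalization and no cell calling, so cells were called here from the deposited UMI counts. Gene identifiers were looked up in GENCODE M21 (GRCm38), which holds 32235 of the 32285 (99.8%), with the same symbol for 97.6%. Group membership was read from the labels. No label pairs a library of one group with one of the other, and replicate numbers were not used as pairs.

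A barcode was kept as a cell with at least 500 UMIs, at least 250 genes and at most 10% mitochondrial UMIs. Within each library the barcodes with the highest Scrublet doublet scores were then removed, at a rate of 0.8% per 1000 barcodes; Scrublet's own threshold called at most 1 barcode per library. Counts were scaled per cell and log-transformed, and 2000 variable genes were chosen across libraries. The interferon, MHC, cell cycle, stress, ribosomal and mitochondrial lists and antigen receptor segments were left out of these, so that clusters would not rest on them. Genes of the other lists could enter. Some markers used for naming were also compared later, such as Prf1 in NK cells, Mrc1 in macrophages and Foxp3 in regulatory T cells. The first 30 principal components and 15 neighbours gave Leiden clusters at resolution 1, with no integration of libraries, and T and NK clusters were clustered a second time (scanpy 1.11.5, igraph 0.11.9, random seed 1). Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used, and matplotlib 3.10.9 for the figures. Clusters were named from marker genes. Each marker's log2 level over the lower quartile of clusters (pseudocount 10 CPM, clusters of at least 50 cells) was divided by its value in its highest cluster, and the class with the highest mean was taken. A cluster stayed unnamed with under 20 cells, under 3 detected markers, a lead under 0.05 over the next class, more markers of another class among its 10 leading genes, myeloid markers leading a T or NK cluster, or Cd4 and Cd8a within a ratio of 0.1 in a T cell cluster. A cluster whose median UMI count was over 3 times below its libraries' medians also stayed unnamed if no marker of its class led it. The markers were fixed before the data were examined, but this scoring was not: 5 scorings were looked at with the clusters and their cell numbers per library in view. The scoring coded before the one used here is kept as an alternative. Unnamed clusters hold 10.2% of iLuc and 30.9% of iIL12 cells and enter the whole population but no class. No cluster was named as conventional CD4 T cells, so the planned comparison of CD8 with CD4 T cells was not run.

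The library, not the cell, was the unit of every test. Shares of kept cells were compared by an exact two-sided permutation test of the difference in means, over the 70 assignments of 4 against 4 libraries, with Benjamini-Hochberg adjustment over the 15 classes. For expression, UMI counts were summed per library over all kept cells, and per library and class. A class was tested with at least 10 cells in at least 3 libraries of each group, which 12 classes met; pDC, gamma-delta T and mast cells did not and were tested for share alone. The sums were fitted with the edgeR quasi-likelihood test (edgeR 4.0.16, TMM, filterByExpr, R 4.3.3), with Benjamini-Hochberg adjustment over all genes of a fit and a threshold of 0.05. The difference of the treatment effect between CD8 T and NK cells, and between macrophages and neutrophils, was tested in edgeR as the interaction of class and group with the library as a block. Each of 23 gene lists was tested with camera (limma 3.58.1) on the fitted counts with a preset correlation of 0.01, adjusted over the lists of a fit. Its members past the threshold were counted once adjusted over all genes and once over the list alone. Camera with a correlation estimated from the samples is given beside it, since the preset one calls far more lists. Fold changes of a gene with no UMI in one group are lower bounds against a floor of 3 UMIs over that group.

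Free RNA, the RNA outside cells that every droplet takes up, was estimated per library and class. Its profile came from barcodes with 100 to under 300 UMIs, and its amount from markers of another lineage: macrophage genes in lymphocytes, CD8 T genes in all other classes. An estimate from haemoglobin genes had failed first, and this one was chosen before any fold change was seen. True expression of those markers raises the estimate, which was limited to 50%. The limit was reached in 2 iIL12 libraries for B cells and 1 iLuc library for fibroblasts among the classes tested for expression.

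The genes named were set by a rule fixed before the data were examined, as were the tests, the lists and the alternatives except those said below to be added. The rule takes the 10 largest rises and 10 largest falls for the whole population, 8 and 8 for the 4 classes with most cells and 2 and 2 for the others. A gene had to pass the threshold, show no overlap between groups in CPM and reach a mean of at least 20 CPM in the higher group. Predicted gene models, receptor segments, Xist and Y-linked genes were left out by name. A panel of 18 genes of the IL-12 response is named for the whole population or the class it bears on, with up to 4 members of the lowest p per list described. Results for 1 panel gene are not reported here. Beside these, a few genes that mark clusters are given, chosen after the clusters were seen.

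The tests were run on simulated data with library sizes and spread taken from these libraries. For folds of 1.5, 2 and 4 edgeR recovered 28.4%, 60.6% and 97% of changed genes in the whole population, with 7.52% of calls false. In macrophages it recovered 30.8%, 73.4% and 97% (5.76% false), and in CD8 T cells 47%, 81.5% and 100% (3.87% false). DESeq2 had 26.6% false calls in the whole population. Camera called 10 of 10 changed lists and 0 of 10 unchanged ones. Genes were simulated independently of one another, and far fewer were changed than were called in these libraries. The simulation therefore does not show how often camera calls unchanged lists whose members are correlated. Permutations of 4 against 4 libraries cannot give a p below 0.0286. Alternatives changed the UMI minimum (1000), the mitochondrial limit (5%), the doublet step, the clustering genes and resolution (2), the share's denominator, the normalization (DESeq2 size factors), the gene filter, the depth (thinning to the lowest library), a block for the replicate number, and the tests (DESeq2 1.42.0, fry, limma voom). A further alternative kept barcodes under 5000 UMIs only if their profile differed from that of barcodes under 100 UMIs (adjusted p under 0.01). Each library was also left out in turn. Alternatives added after the data were seen are listed in the last section.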

Results

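Single-cell RNA was read from viable CD45+ cells sorted from mouse tumours 6 days after treatment. CD45 is the surface protein of leukocytes. The tumours had received 8 Gy of radiotherapy (RT) with an adeno-associated virus (AAV), either AAV-iLuc as the control or AAV-iIL12 as the treatment. The labels name the inserts iLuc and iIL12 and do not spell them out further. Each group held 4 libraries. The libraries were 10x 3' libraries, in which each captured RNA molecule carries a unique molecular identifier (UMI), and values are UMI counts mapped to mm10. Total UMIs per library ran from 97965422 to 103690482 in the iLuc group and from 110368354 to 130381885 in the iIL12 group. Kept cells per library numbered 5175 to 7042 in iLuc and 5643 to 6791 in iIL12, 49007 in all. Median UMIs per kept cell were 8074.5 to 12718 in iLuc and 11994 to 13429 in iIL12. No label gives a preparation or sequencing batch, and nothing says that the 4 libraries of a group came from separate animals. The sequencing samples are numbered 1 to 4 anew within each group, so each group may have had its own run, and then run and group cannot be told apart. The p-values therefore measure only the spread between these samples. Group values below are means ± SD over the 4 libraries of a group unless stated, log2 fold changes are ± SE, and every difference is iIL12 relative to iLuc.

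The first question was which cells made up the sorted population. Conventional and migratory dendritic cells, which present antigen to T cells, fell from 15.9% ± 2.67 to 1.85% ± 0.329 of kept cells. Type 2 conventional dendritic cells (cDC2) fell 16.8-fold, from 7.35% ± 0.926 to 0.439% ± 0.178, but the size of this fall depended on the clustering: it was 2.54-fold, from 7.89% ± 0.947 to 3.1% ± 0.454, with all variable genes and 5.81-fold, from 7.54% ± 0.66 to 1.3% ± 0.138, with doublets kept. Migratory dendritic cells fell 7.31-fold, from 3.98% ± 1.13 to 0.545% ± 0.193, and plasmacytoid dendritic cells (pDC) fell 8.22-fold, from 1.26% ± 0.577 to 0.153% ± 0.0717. Type 1 conventional dendritic cells (cDC1) fell 5.22-fold, from 4.54% ± 1.19 to 0.87% ± 0.0935. B cells fell from 1.1% ± 0.50 to 0.283% ± 0.0786 and gamma-delta T cells from 0.127% ± 0.0558 to 0.0211% ± 0.0163. Natural killer (NK) cells rose from 4.88% ± 0.411 to 6.64% ± 0.727, a rise no longer called at a Leiden resolution of 2. Cells with tumour or melanocytic markers, a type without CD45, fell from 1.69% ± 0.545 to 0.425% ± 0.326. Cluster 27, named for its fibroblast markers, went from 4.33% ± 6.0 to 0.265% ± 0.177. Its median was 806 UMIs per cell, its iLuc cells held more melanocytic transcripts (Dct at 5123 and Tyrp1 at 1398 CPM) than Sparc (299.6) or Fn1 (156), and an earlier naming rule left it unnamed, so its cells may not be fibroblasts. These 9 differences each reached the smallest p that 70 exact two-sided permutations of 4 against 4 libraries allow, 0.0286, with adjusted p = 0.0476 over 15 classes. For cluster 27 the call was lost with a UMI minimum of 1000 (-1.67 percentage points, adjusted p = 0.117), and without iLuc replicate 3, which held most of its cells, the difference was -1.1 against -4.06 points. CD8 T cells went from 2.08% ± 1.12 to 6.02% ± 3.06 (exact permutation p = 0.114) and macrophages from 36.7% ± 7.15 to 28.4% ± 3.67 (exact permutation p = 0.0571), neither past the adjusted threshold. Monocytes (19.2% ± 3.12 to 23.4% ± 6.93), neutrophils (1.5% ± 0.547 to 0.684% ± 0.18), regulatory T cells (1.06% ± 0.626 to 0.89% ± 0.402) and mast cells (0.0799% ± 0.0771 to 0% ± 0) were not called either, with exact permutation p of 0.486, 0.0571, 0.714 and 0.143. Other choices of cells or clusters changed 4 of these calls, in percentage points: CD8 T cells 9.98 with doublets kept and 9.54 with unnamed clusters placed in their best class, macrophages -29 with doublets kept, -12.9 at a Leiden resolution of 2 and -18.7 with all variable genes, monocytes 23.4 with all variable genes and 17.5 with unnamed clusters placed, and neutrophils -0.894 at 1000 UMIs, -0.842 with the ambient test and -0.829 with at most 5% mitochondrial UMIs. Several of these rest on the naming of clusters. With doublets kept, CD8 T cells include cluster 102 (1421 iIL12 and 19 iLuc cells), led among T and NK cells by the myeloid genes Nos2 and Acod1, and without it their difference is 4.65 points (exact permutation p = 0.0857). A cluster led by Nos2 (5050 iIL12 and 88 iLuc cells), like one that counts as macrophages in the main clustering, goes unnamed there, and with it macrophages differ by -9.86 points (exact permutation p = 0.114). With unnamed clusters placed, CD8 T cells gain a cluster led by myeloid genes, and without it their difference is 6.53 points (exact permutation p = 0.0857). Without iIL12 replicate 2 the monocyte difference was 0.783 points. Class names stand for clusters with those markers and are used as short names from here on.

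Clusters that met no naming rule rose from 10.2% ± 3.55 to 30.9% ± 7.54 of cells (exact permutation p = 0.0286), so the shares of named classes leave out more cells in iIL12. Counted over named and unnamed clusters, all T and NK clusters rose from 12.4% ± 1.25 to 23.2% ± 7.14 (exact permutation p = 0.0286). The named monocyte and macrophage classes alone went from 55.8% ± 9.58 to 51.8% ± 10.3 (exact permutation p = 0.629), with unnamed cluster 2 from 56.1% ± 9.74 to 65.4% ± 9.34 (exact permutation p = 0.257), and with each unnamed cluster whose best class was monocyte or macrophage from 59.6% ± 8.76 to 73% ± 7.24 (exact permutation p = 0.0571). Unnamed cluster 2 rose from 0.265% ± 0.165 to 13.6% ± 2.19, and 94.1% of its cells held UMIs of the monocyte marker Ly6c2. This gene was also in 92.4% of CD8 T cluster 114 and 90% of pDC, but in 30.7% of cDC1, so it does not mark monocytes alone. Cluster 2 held Clec9a UMIs in 29.8% of its cells, against 94.5% of cDC1. Its share with Xcr1 was 3.02%, against 88.2% of cDC1. The B cell gene Cd79a was in 0.0888% of cluster 2 cells, at a median of 12524 UMIs against 20412 in cDC1. Unnamed clusters 112 and 116, whose cells held Cd3e and Cd8a UMIs, were 0% and 0% of iLuc cells and 2.76% ± 2.44 and 2.32% ± 0.695 of iIL12 cells. Without iIL12 replicate 1 the mean of cluster 112 was 1.56%. Unnamed cluster 1, with a median of 636 UMIs per cell, went from 3.46% ± 1.67 to 7.55% ± 5.15 (exact permutation p = 0.143). Many named clusters were also close to specific to a group. Among monocytes, cluster 5 was 18.8% of iLuc and 0.209% of iIL12 cells, and cluster 16 0.195% and 18.4%. Among macrophages, cluster 3 was 14.7% and 0.274%, and cluster 14 0.559% and 20.8%. Among CD8 T cells, cluster 104 was 2.04% and 0.218%, and cluster 111 0.0384% and 2.21%. Among NK cells, cluster 101 was 4.78% and 0.0569%, and cluster 109 0.0369% and 3.31%. The iIL12 means of clusters 5 and 3 were 0.0999% and 0.138% without iIL12 replicate 2, and that of cluster 104 0.143% without iIL12 replicate 4. Expression differences within a class thus compare cell states that the groups shared only in part. As a share of T and NK cells NK cells went the other way, by -8.82 percentage points (exact permutation, adjusted p = 0.286). With an earlier naming rule, or as shares of named immune cells, 7 of the falls and rises had adjusted p = 0.0531 or more.

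**Figure D1:**
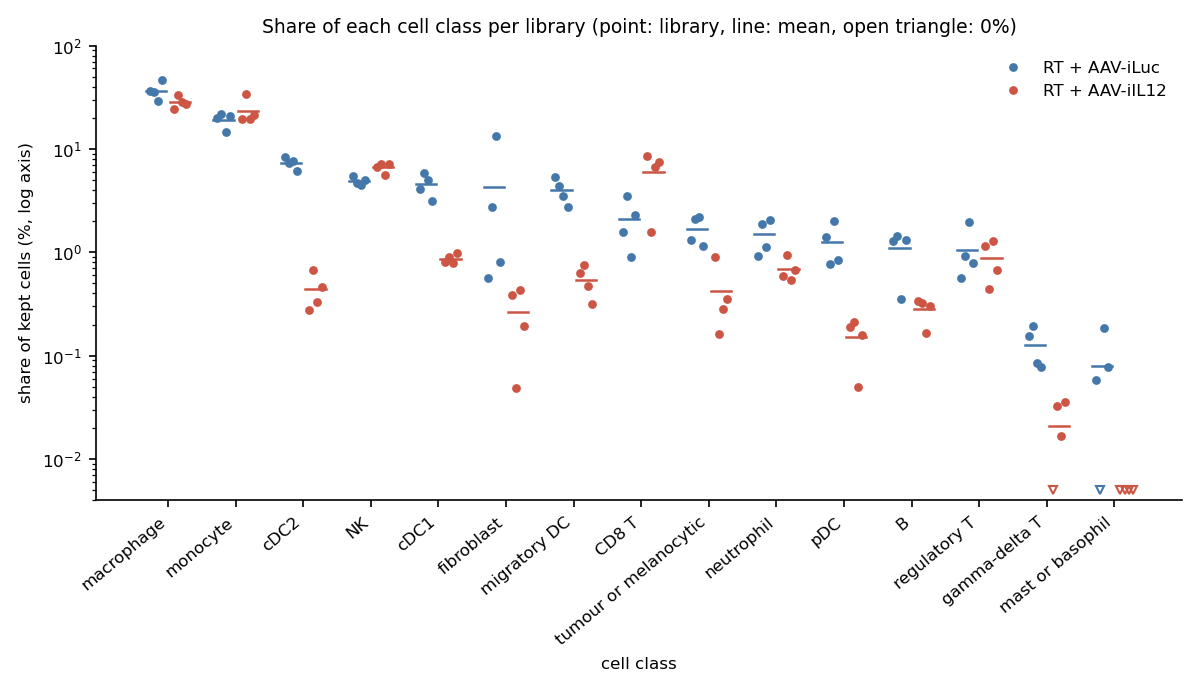
Share of kept cells (%, log axis) of each class in each of the 4 iLuc and 4 iIL12 libraries, with a line at each group's mean. In the cDC1, cDC2, migratory DC and pDC classes every iLuc point lies above every iIL12 point, and in NK cells every iIL12 point lies above every iLuc point.

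The whole sorted population was compared next, to ask how its pooled transcripts differed after AAV-iIL12. Ifng, the gene of interferon gamma (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892 of GRCm38/mm10), rose 112-fold, from 6.69 ± 1.6 to 752 ± 318 CPM (counts scaled to a common library total, n = 4 per group, adjusted p = 7.93e-06). Among the 10 largest rises were also Gbp2b (54.3-fold), Iigp1 (27.4-fold) and Serpina3f (22.7-fold), which interferon gamma induces, Gzmf (48.7-fold), which encodes a granzyme, and Ly6i (22.5-fold). P2rx3 (204-fold), Slc17a6 (38.6-fold), Mt3 (24.6-fold) and Prm1 (23.9-fold), known mainly from neurons and spermatids, completed them. The largest fall was that of Cd209a (ENSMUSG00000031494, chromosome 8, 3743397 to 3748984), a lectin of dendritic cells, 88.8-fold, from 58.8 ± 13.2 to 0.666 ± 0.679 CPM (adjusted p = 4.34e-05). The macrophage and dendritic cell genes Mgl2 (22-fold), Retnla (21.6-fold) and Pf4 (18.3-fold) and the pDC gene Siglech (12-fold) fell too, as did Adam12 (23.1-fold), Fbxl7 (18.5-fold), Ano3 (17.6-fold), Pde10a (14.8-fold) and Nav3 (12.2-fold), the last not called among named immune cells alone (log2 fold change -1.02). Il12b, the subunit shared by IL-12 and IL-23 (ENSMUSG00000004296, chromosome 11, 44400063 to 44414033), fell 5.53-fold, from 39.9 ± 10.6 to 7.21 ± 3.63 CPM (adjusted p = 4.23e-04), while Il12a stayed near 0.897 and 0.844 CPM (adjusted p = 0.844). Both IL-12 receptor genes rose, Il12rb1 10.6-fold and Il12rb2 4.31-fold. Tbx21, a Th1 transcription factor, rose 3.0-fold. Of the killing genes Gzmb rose 12.1-fold and Prf1 10.8-fold. Cxcl9 rose 6.18-fold, Cxcl10 7.37-fold, Cd274, which encodes PD-L1, 3.21-fold, Il10 2.0-fold and Nos2 12.2-fold, and Arg1 fell 2.48-fold. Stat4 (adjusted p = 0.0587), Foxp3 (adjusted p = 0.392) and the proliferation gene Mki67 (adjusted p = 0.128) did not pass the threshold. Stat4 was called lower in 6 alternatives, from log2 -0.44 with the replicate block to -1.12 among named immune cells alone, with -0.54 without iLuc replicate 4 and -0.55 without iIL12 replicate 1. Mki67 was called higher among named immune cells alone (0.76) and without iIL12 replicate 2 (0.60). In all, 4028 rose and 4201 fell of 16928 tested genes, at class sums of 77385476 to 97025343 UMIs per library. The values of the groups did not overlap in 7628 (45.1%, against 2.86% by chance) genes. Each gene named as rising or falling here had adjusted p of 0.00332 or less.

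Grouped by lists fixed in advance, the interferon gamma response rose across the population: 31 of 31 measured members rose, 31 adjusted over the list alone, with a median log2 fold change of 2.40 (adjusted p = 6.32e-39, and adjusted p = 0.141 with an estimated correlation). In MHC class I presentation 19 of 19 measured members rose, 19 adjusted over the list alone (adjusted p = 1.35e-18, and adjusted p = 0.193 with an estimated correlation). In the cytotoxic effector list 16 of 20 measured members rose, 16 adjusted over the list alone (adjusted p = 4.87e-18, and adjusted p = 0.0995 with an estimated correlation). The IL-12 and Th1 pathway rose, with 13 of 16 members higher (adjusted p = 5.18e-15, and adjusted p = 0.0995 with an estimated correlation). Smaller rises, none called with an estimated correlation, were called in type I interferon response (15 and 1 of 22, adjusted p = 4.52e-07), MHC class II presentation (9 and 2 of 12, adjusted p = 0.00854), macrophage inflammatory (10 and 2 of 17, adjusted p = 0.0017), inflammasome and NF-kB (11 and 1 of 20, adjusted p = 1.82e-04), cell cycle (8 and 0 of 30, adjusted p = 0.0349) and ribosomal protein genes (4 and 0 of 33, adjusted p = 0.0297), where the first 2 counts are members that rose and fell. The macrophage alternative and tissue repair list fell (2 and 16 of 23, adjusted p = 2.31e-05), with Ccl22 7.29-fold and Ccl17 10.8-fold lower, and so did the tumour and melanocytic list (0 and 8 of 11, adjusted p = 1.11e-04), beside the fall in the share of those cells. Not called were T cell exhaustion (8 and 1 of 15, adjusted p = 0.139), naive and memory T cell (5 and 5 of 12, adjusted p = 0.885), regulatory T cell (8 and 2 of 13, adjusted p = 0.0741), chemokines (4 and 9 of 21, adjusted p = 0.328), p53 and DNA damage response (6 and 3 of 19, adjusted p = 0.364), hypoxia and glycolysis (3 and 10 of 22, adjusted p = 0.121), dissociation and stress (5 and 4 of 24, adjusted p = 0.978), mitochondrially encoded (0 and 2 of 11, adjusted p = 0.996), fibroblast (1 and 3 of 7, adjusted p = 0.565), endothelial (2 and 4 of 8, adjusted p = 0.565) and erythroid (0 and 3 of 4, adjusted p = 0.192). None of the 12 calls held with an estimated correlation between the members. For cell cycle and ribosomal protein genes the exact permutation p of the list mean was 0.229 and 0.114. These values mix changed shares of cells with changed expression.

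Macrophages were compared to ask how this largest class responded. Iigp1, an interferon-induced GTPase (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634), rose 25.4-fold, from 37.6 ± 3.05 to 957 ± 113 CPM (n = 4 per group, adjusted p = 1.19e-08). Gbp2b (80.5-fold), Dnase1l3 (48.7-fold), Chrm3 (29.8-fold) and Majin (28.5-fold) were also among the 8 largest rises. Nos2, which makes nitric oxide (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), rose 12.7-fold, from 72.3 ± 38.5 to 918 ± 31 CPM, and Arg1, which uses the same substrate, fell 2.26-fold (adjusted p = 6.93e-05 and 2.91e-04). The fall of Arg1 was not called with doublets kept (log2 fold change -0.20) or at a Leiden resolution of 2 (-0.33). The 8 largest falls were Fcrls 156-fold, Gas6 35.3-fold, Ltc4s 22.2-fold, Retnla 20.2-fold, Pf4 18.3-fold, Apoe 16.6-fold, Igf1 16.1-fold and St6gal1 15.2-fold. Without iLuc replicate 3, where they were highest, the log2 fold changes of Fcrls, Gas6 and Igf1 were -6.19, -4.11 and -2.98, against -7.28, -5.14 and -4.01 with it. Retnla went from -4.33 to -7.48 without iIL12 replicate 3, where it was highest. In MHC class II presentation 12 of 12 measured members rose, 12 adjusted over the list alone, among them H2-Ab1 3.52-fold and H2-Eb1 3.52-fold (adjusted p = 1.25e-12, and adjusted p = 0.109 with an estimated correlation). Across the interferon gamma response 31 of 31 measured members rose, 31 adjusted over the list alone (adjusted p = 2.42e-53, and adjusted p = 0.052 with an estimated correlation), and Cxcl9 and Cxcl10 rose 6.01-fold and 6.51-fold. The macrophage inflammatory list rose, with Cd40 4.72-fold and Ccl5 7.68-fold higher (adjusted p = 6.86e-08, and adjusted p = 0.213 with an estimated correlation), and the alternative and tissue repair list fell, with 16 of 23 members lower, Mrc1 6.67-fold and Ccl24 13.6-fold among them (adjusted p = 1.59e-06, and adjusted p = 0.0755 with an estimated correlation). Il12rb1 rose 10.6-fold and Il12rb2 5.87-fold.

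Lymphocyte genes rose in macrophages too. Gzmf went from 0.276 ± 0.223 to 32.1 ± 21 CPM, Ifng from 0.482 ± 0.343 to 42 ± 14.8 CPM and Gzmc from 0.832 ± 0.254 to 23.3 ± 4.65 CPM, and in the cytotoxic effector list 17 of 20 measured members rose and 0 fell, 17 and 1 adjusted over the list alone (adjusted p = 1.54e-16, and adjusted p = 0.00395 with an estimated correlation). NK cells of iIL12 tumours held 2554 CPM of Gzmf. Free RNA, estimated from other lineages' markers, was 6.43% ± 4.12 in iLuc and 1.91% ± 0.298 in iIL12 of macrophage UMIs. Its subtraction left 0.0266, 0.0259 and 0.0586 of the differences in CPM of Gzmf, Ifng and Gzmc, too few UMIs to test them, while the 9 members still measured had adjusted p = 5.64e-04. The melanocytic genes Dct and Tyrp1 changed by log2 -2.04 and -1.79, and free RNA subtraction left no UMI of either in iLuc, so no fold is given after it. In all, 2855 rose and 2940 fell of 13308 tested genes in 15907 macrophages with 22740837 to 34844478 UMIs per library, and 5548 (41.7%, against 2.86% by chance) did not overlap between groups. The genes named above as rising or falling in macrophages had adjusted p of 0.00685 or less. Of the 10 lists called, cytotoxic effector and the IL-12 and Th1 pathway held with an estimated correlation.

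Monocytes, the precursors of many tumour macrophages, also showed an interferon response; its difference from that of macrophages was not tested. Iigp1 rose 76-fold, from 21.4 ± 9.19 to 1650 ± 249 CPM (n = 4 per group, adjusted p = 5.38e-08), and Gbp2b 48.4-fold, Serpina3f 32.4-fold and Dnase1l3 28.6-fold. In MHC class II presentation 12 of 12 measured members rose, 12 adjusted over the list alone; Cd74, the invariant chain (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), rose 6.71-fold and H2-Eb1 8.58-fold (adjusted p = 1.04e-13, and adjusted p = 0.101 with an estimated correlation). In MHC class I presentation 19 of 19 measured members rose, 19 adjusted over the list alone, with H2-Q7 8.56-fold higher (adjusted p = 1.05e-25, and adjusted p = 0.0303 with an estimated correlation). Of the interferon gamma response, 31 of 31 measured members rose, 31 adjusted over the list alone (adjusted p = 3.93e-47, and adjusted p = 0.0303 with an estimated correlation). Apoe fell 10.8-fold (log2 -4.49 without iIL12 replicate 2, against -3.44), and the chemokine gene Cxcl3 10.8-fold. Hspa1b, Fabp4, Rnf150 and Dpep2 fell 8.79-fold, 8.65-fold, 7.33-fold and 6.86-fold. Ddit4 and Egln3, which hypoxia induces, fell 7.51-fold and 6.86-fold, within a fall of the hypoxia and glycolysis list in which 12 of 21 members fell and 3 rose (adjusted p = 3.94e-04, and adjusted p = 0.348 with an estimated correlation). Nos2 rose 15.6-fold and Arg1 fell 4.31-fold. The alternative and tissue repair list fell on balance (13 lower, 3 higher; adjusted p = 0.00287, and adjusted p = 0.252 with an estimated correlation), yet its complement members C1qb and C1qc rose 6.83-fold and 7.42-fold. Stat4 fell 3.94-fold. Ifng, Gzmf, Gzmc and Gzma again rose, Gzma from 0.912 ± 0.552 to 25.4 ± 1.39 CPM, with 15 of 19 cytotoxic members higher (adjusted p = 9.30e-17, and adjusted p = 0.0295 with an estimated correlation). Free RNA was 2.59% ± 1.47 in iLuc and 2.35% ± 0.439 in iIL12 of monocyte UMIs. Its subtraction left 0.0367 and 0.109 of the differences in CPM of Gzmf and Gzma and none of those of Ifng and Gzmc, too few UMIs to test any of the 4, while the 9 members still measured had adjusted p = 0.00855. In all, 2857 rose and 2756 fell of 11734 tested genes in 10368 monocytes with 8023604 to 26170489 UMIs per library, and 5110 (43.5%, against 2.86% by chance) did not overlap. Named rises and falls in monocytes had adjusted p of 5.46e-04 or less. Of the 13 lists called, interferon gamma response, MHC class I presentation, cytotoxic effector and the IL-12 and Th1 pathway held with an estimated correlation.

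**Figure D2:**
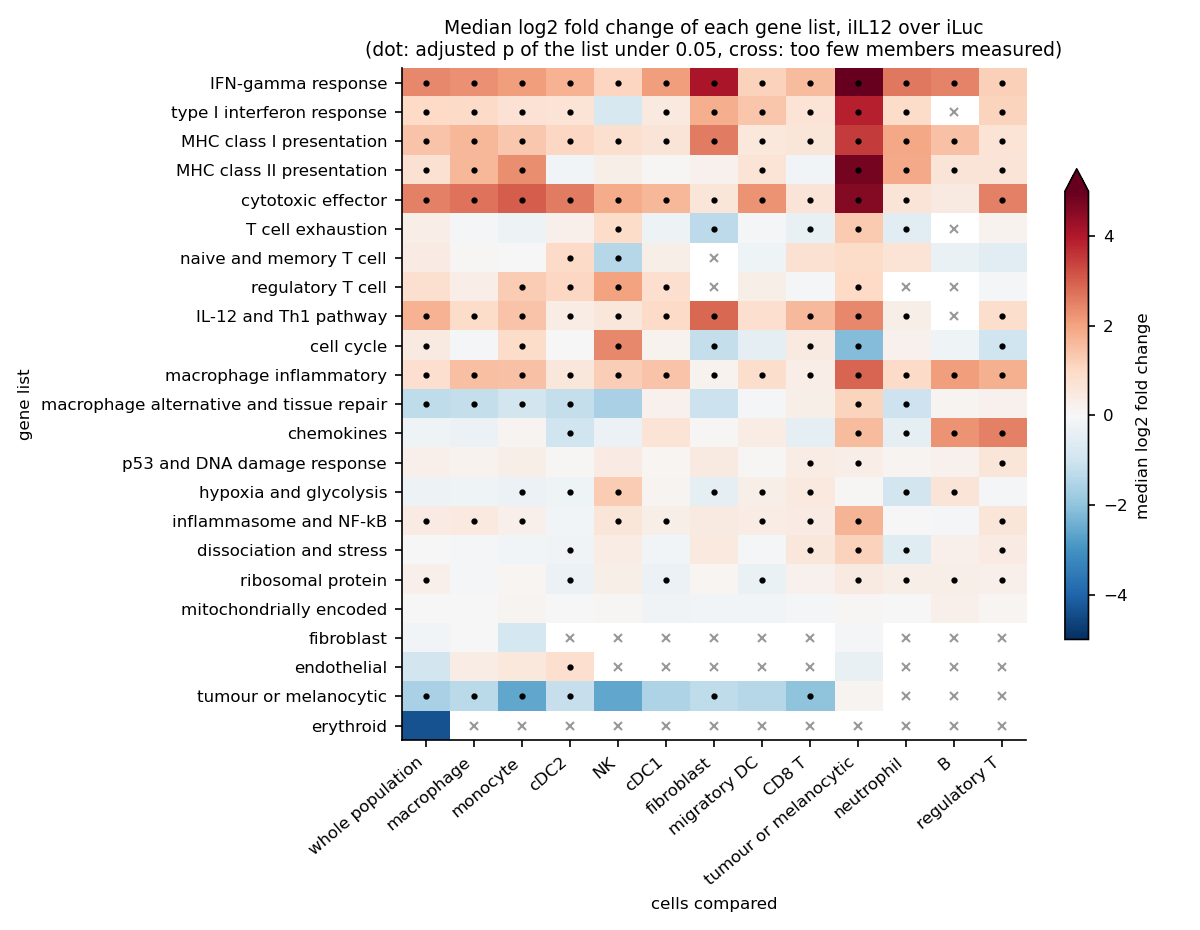
Median log2 fold change (iIL12 relative to iLuc, colour scale) of the measured members of each fixed gene list in the whole population and in each class, with a dot where the list was called. The interferon gamma response and MHC class I lists are above 0 in each column drawn.

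NK cells were compared because IL-12 acts on them directly. Gzmf (ENSMUSG00000015441, chromosome 14, 56205263 to 56211417), scarcely read in iLuc, rose 4152-fold, from 0.601 ± 0.278 to 2554 ± 406 CPM (n = 4 per group, adjusted p = 1.00e-14). Of the established killing genes, Gzmb rose 7.35-fold and Prf1, the gene of perforin (ENSMUSG00000037202, chromosome 10, 61297833 to 61304680), 5.63-fold, from 592 ± 108 to 3330 ± 329 CPM (adjusted p = 1.83e-09). Ifng rose 27.5-fold, and in the cytotoxic effector list 14 of 20 measured members rose and 2 fell, 14 and 2 adjusted over the list alone (adjusted p = 2.92e-10, and adjusted p = 0.134 with an estimated correlation). Il10, a cytokine gene that restrains immune responses, rose 90.9-fold, from 0.98 ± 0.466 to 87.9 ± 28.7 CPM. Il1rl1, the IL-33 receptor, rose at least 70.8-fold from no UMI in iLuc, Ifitm1 202-fold and Mecom 93.4-fold (log2 8.58 without iLuc replicate 3, against 6.55). P2rx3 went from 0.349 ± 0.242 to 87.4 ± 18.1 CPM, Upk1a from 0.118 ± 0.236 to 21.4 ± 9.48 CPM and Timp3 from 0.236 ± 0.473 to 26.2 ± 21.9 CPM. The NK class also had a more dividing profile in iIL12, with 30 of 30 cell cycle members higher (30 adjusted over the list alone), Mki67 4.46-fold and Top2a 4.85-fold among them (adjusted p = 3.02e-21, and adjusted p = 0.117 with an estimated correlation). Glycolytic genes rose, Gapdh 3.98-fold and Pkm 3.76-fold (adjusted p = 1.00e-06, and adjusted p = 0.216 with an estimated correlation). In the naive and memory list 10 of 11 measured members fell, 10 adjusted over the list alone, with Tcf7 33.4-fold and Ccr7 18.4-fold lower (adjusted p = 4.63e-08, and adjusted p = 0.0101 with an estimated correlation). IL-12 signalling genes moved apart: Il12rb1 rose 4.36-fold, while Il12rb2, the signalling chain of the receptor, fell 2.06-fold, Stat4 3.58-fold and Tbx21 1.37-fold. The regulatory T cell list rose through Capg 7.27-fold, Il2ra 28-fold, Il10 and Tnfrsf9 3.65-fold, which activated NK cells express too (adjusted p = 3.80e-07, and adjusted p = 0.126 with an estimated correlation). Btbd11 67-fold (log2 -7.07 without iIL12 replicate 2, against -6.07), Hvcn1 56.5-fold, Angpt1 49.9-fold, Plxnc1 40.2-fold, Slc26a11 37.1-fold, Fgf13 35.2-fold, Fhit 33.9-fold and the macrophage gene Pf4 41-fold were the largest falls. In all, 3358 rose and 3294 fell of 10500 tested genes in 2816 NK cells with 1690296 to 6900809 UMIs per library, and 6017 (57.3%, against 2.86% by chance) did not overlap. Named rises and falls in NK cells had adjusted p of 0.00259 or less. Of the interferon gamma response members, 21 of 25 rose and 1 fell (adjusted p = 1.24e-07, and adjusted p = 0.0101 with an estimated correlation); this list and the naive and memory list held with an estimated correlation, of 11 called.

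CD8 T cells are the other main killers of tumour cells. Ifng rose 21.4-fold, from 121 ± 26.1 to 2561 ± 810 CPM (n = 4 per group, adjusted p = 1.92e-08), but Gzmb (adjusted p = 0.0932) and Prf1 (adjusted p = 0.384) did not pass the threshold, and the granzyme genes Gzmd (ENSMUSG00000059256, chromosome 14, 56129556 to 56132608) and Gzme fell 43.3-fold and 40.2-fold. With unnamed clusters placed in their best class, at a Leiden resolution of 2 or with all variable genes, the latter 2 falls were not called and Gzmb rose. The cytotoxic effector list rose by camera (adjusted p = 0.00962, and adjusted p = 0.446 with an estimated correlation), with 10 of 20 members higher and 3 lower, but its mean did not separate the groups (exact permutation p = 0.171). Furin, which IL-12 induces in T cells, rose 54.7-fold, Il12rb1 3.51-fold and Il12rb2 2.44-fold, within an IL-12 and Th1 pathway in which 13 of 16 members rose and 3 fell (adjusted p = 1.85e-14, and adjusted p = 0.0433 with an estimated correlation). Eomes fell 5.74-fold and Stat4 1.43-fold. Tox, a regulator of exhausted T cells (ENSMUSG00000041272, chromosome 4, 6686353 to 6991557), fell 4.38-fold, from 576 ± 114 to 132 ± 53.6 CPM, and 8 of 15 exhaustion members fell while 3 rose (adjusted p = 0.033, and adjusted p = 0.446 with an estimated correlation). Il10 rose 15.2-fold and Cxcl10 11.6-fold. Prnp rose 356-fold, Pde5a 106-fold and Fes 57.2-fold. Mecom went from 0.0598 ± 0.12 to 459 ± 51.6 CPM, Timp3 rose at least 230-fold and Irx3 at least 113-fold from no UMI in iLuc, P2rx3 went from 0.41 ± 0.671 to 76.7 ± 8.49 CPM, and P2rx7 from 0.295 ± 0.353 to 44.1 ± 10.9 CPM. Ccr7, which guides T cells to lymph nodes, fell 42-fold. Galnt18 fell at least 399-fold to no UMI, Ccl1 went from 45.6 ± 38.6 to 0.0255 ± 0.0511 CPM, and Mef2c, Slc16a11 and Atp2b2 fell 55.1-fold, 52-fold and 46.4-fold. Without iIL12 replicate 1 the log2 fold change of Slc16a11 was -6.96, against -5.70. The hypoxia and glycolysis list rose, with Hif1a 2.65-fold higher (adjusted p = 1.59e-04, and adjusted p = 0.403 with an estimated correlation). The early response genes Jun and Egr1, which cell dissociation also induces, rose 6.42-fold and 8.32-fold (adjusted p = 9.28e-05, and adjusted p = 0.235 with an estimated correlation). For the interferon gamma response, 23 of 25 measured members rose, 23 adjusted over the list alone (adjusted p = 4.89e-22, and adjusted p = 0.0433 with an estimated correlation). In all, 2323 rose and 2265 fell of 10167 tested genes in 1982 CD8 T cells with 1253394 to 11023662 UMIs per library, and 4007 (39.4%, against 2.86% by chance) did not overlap. Named rises and falls in CD8 T cells had adjusted p of 0.00755 or less. Of 13 lists called, the interferon gamma response and the IL-12 and Th1 pathway held with an estimated correlation. Unnamed clusters with Cd3e and Cd8a UMIs are not part of this class.

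Whether NK and CD8 T cells differed in their response was tested as an interaction, the log2 fold change in NK cells minus that in CD8 T cells. Gzmb differed by 2.42 ± 0.23 (adjusted p = 4.65e-07), Prf1 by 2.75 ± 0.17 (adjusted p = 4.90e-09) and Mki67 by 1.98 ± 0.29 (adjusted p = 4.13e-05), each with a higher change in NK cells. Gzmb and Prf1 were not called within CD8 T cells. Unnamed cluster 112, with Cd3e and Cd8a UMIs and Gzmf and Gzmb among its leading genes, is not part of the CD8 T class. With unnamed clusters placed in their best class Gzmb rose in CD8 T cells (log2 1.09), and the interaction was not run on those classes. Il12rb2 differed by -2.37 ± 0.18 (adjusted p = 7.14e-08), since it fell in NK and rose in CD8 T cells. Stat4 differed by -1.32 ± 0.12, Tbx21 by -0.85 ± 0.11, Cd274 by -0.83 ± 0.15 and Cxcl10 by -1.82 ± 0.26. Il10 differed by 2.41 ± 0.59 and Cxcl9 by 1.93 ± 0.76 with edgeR, but with voom, another model of the same counts, their adjusted p were 0.154 and 0.676. Ifng (adjusted p = 0.139), Il12rb1 (adjusted p = 0.141) and Nos2 (adjusted p = 0.92) did not differ between these cells. In all, 4862 of 11071 genes differed, 2845 with a higher change in NK cells. Free RNA was 4.01% ± 1.8 in iLuc and 2.37% ± 0.415 in iIL12 of NK cell UMIs. In CD8 T cells it was 1.55% ± 0.542 and 2.03% ± 0.32. The interaction was not run with free RNA subtracted. Between macrophages and neutrophils 302 of 12570 genes differed, 78 with a higher change in neutrophils. Nos2 differed by -1.68 ± 0.36 and Arg1 by -2.10 ± 0.44, neither past the threshold with voom (adjusted p = 0.522 and 0.0666).

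**Figure D3:**
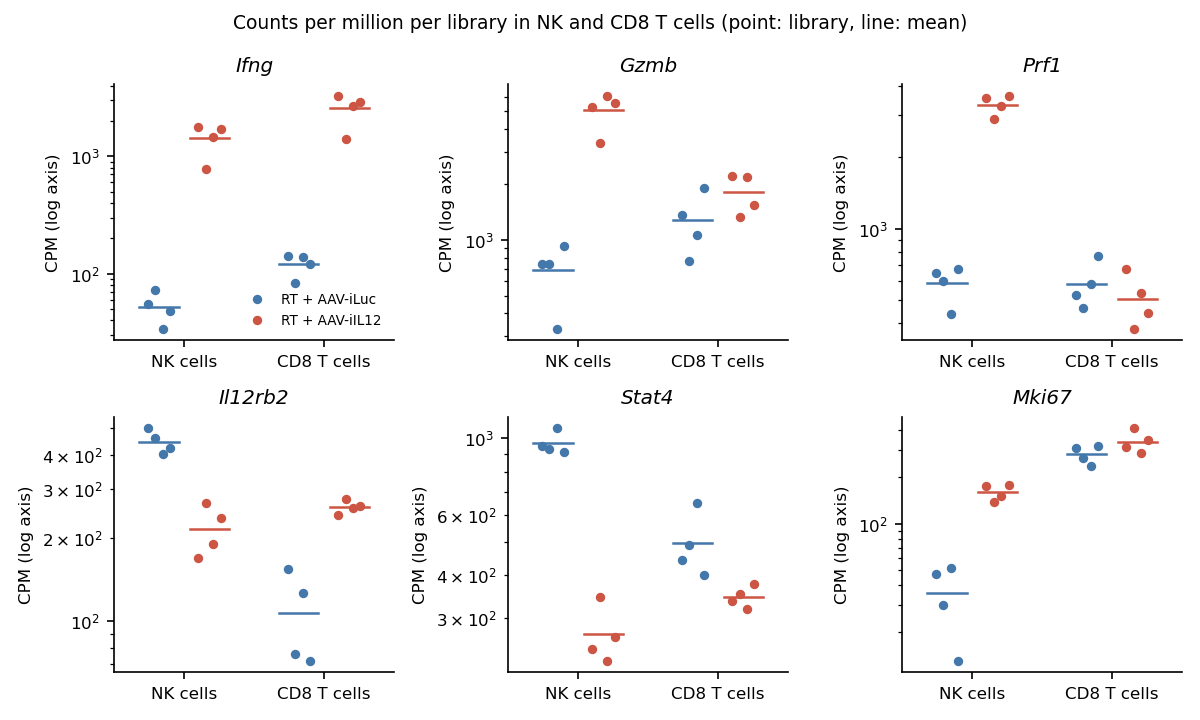
CPM (log axis) of Ifng, Gzmb, Prf1, Il12rb2, Stat4 and Mki67 in each library's NK and CD8 T cells, with a line at each group's mean. Ifng rises in both cell types, while Gzmb and Prf1 separate the groups in NK cells only.

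The dendritic cells of each group were compared to ask how they differed beyond their share. The cDC2 class held 1784 iLuc and 107 iIL12 cells. In iIL12, cDC2 were 3.1% of cells with all variable genes, 1.3% with doublets kept and 0.339% at a Leiden resolution of 2, against 0.439% here. The cDC2 values below may thus cover only part of the iIL12 cDC2. Cxcl9, which draws T cells, rose 5.64-fold in cDC1, 3.31-fold in cDC2 and 3.01-fold in migratory dendritic cells, and Cd274 rose 2.84-fold, 2.64-fold and 1.85-fold. The rise of Cxcl9 was no longer called in cDC2 at a Leiden resolution of 2 (log2 fold change 0.98) and in migratory cells without iIL12 replicate 2 (1.19). Il12b, which fell in the whole population, passed the threshold within none of the 3 classes. In cDC1 it went from 13.6 ± 9.02 to 52.1 ± 64.9 CPM (adjusted p = 0.0565, n = 4 per group), just short of the threshold, in cDC2 it hardly moved (adjusted p = 0.998), and in migratory dendritic cells, where its level was highest of the 3, it went from 1097 ± 234 to 1009 ± 453 CPM (adjusted p = 0.784). Interferon gamma response genes rose in each: 28 of 29 measured members rose, 29 adjusted over the list alone in cDC1 (adjusted p = 3.39e-57, and adjusted p = 0.0114 with an estimated correlation), 27 of 30 measured members rose, 30 adjusted over the list alone in cDC2 (adjusted p = 3.92e-74, and adjusted p = 0.00416 with an estimated correlation) and 27 of 29 measured members rose, 28 adjusted over the list alone in migratory dendritic cells (adjusted p = 1.94e-31, and adjusted p = 0.053 with an estimated correlation). Nos2 rose 51.5-fold in cDC1 and 48.4-fold in migratory dendritic cells. In cDC2, Tbx21 rose 4.05-fold and Il12rb2 6.95-fold, and the repair gene Mrc1 fell 8.73-fold; its largest falls were St6gal1, to 0.955 CPM from 20.9, and Clec4b1 (22.7-fold). In cDC1 the macrophage genes Pf4 and Apoe fell 48.8-fold and 26.1-fold, with log2 -7.17 against -5.61 without iIL12 replicate 3 and -5.79 against -4.71 without iIL12 replicate 2. In migratory dendritic cells Clu fell at least 19.6-fold to no UMI, Ceacam15 went from 28.7 ± 19.2 to 0.879 ± 1.76 CPM, and MHC class II members rose (10 of 12, adjusted p = 1.15e-09, and adjusted p = 0.0667 with an estimated correlation). Of 33 ribosomal protein genes 17 fell in cDC1 (adjusted p = 3.59e-07, and adjusted p = 0.629 with an estimated correlation), 3 in cDC2 (adjusted p = 9.20e-06, and adjusted p = 0.506 with an estimated correlation) and 16 in migratory cells (adjusted p = 7.70e-10, and adjusted p = 0.348 with an estimated correlation), and none rose. The largest rises in each class were lymphocyte genes: Ifng to 25.5 CPM in cDC1, 37.3 in cDC2 and 100.4 in migratory cells, from 0, 0.205 and 0.489; Gzmf to 27.5 in cDC1 and 31 in migratory cells, and Gzmc to 20.9 in cDC2. In cDC1 the log2 fold change of Gzmf was 5.15 without iIL12 replicate 1 and 7.32 without iLuc replicate 2, against 6.31. After free RNA was subtracted the cytotoxic list had adjusted p = 0.196 in cDC1, 0.879 in cDC2 and 0.0428 in migratory cells. Genes that rose and fell numbered 979 and 1045 of 9517 in cDC1 at 1124685 to 7402112 UMIs per library, 552 and 456 of 9525 in cDC2 at 215796 to 7302419, and 726 and 615 of 7544 in migratory cells at 298612 to 4612049; 2356 (24.8%, against 2.86% by chance), 1674 (17.6%, against 2.86% by chance) and 1691 (22.4%, against 2.86% by chance) did not overlap. Named rises and falls had adjusted p of at most 0.011 in cDC1, 4.97e-04 in cDC2 and 0.0113 in migratory cells. Lists called were 9, 15 and 9, of which 3, 6 and 1 held with an estimated correlation.

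Neutrophils, regulatory T cells and B cells are smaller classes. In neutrophils Iigp1 rose 52.8-fold and Cd274 2.84-fold (from 709 ± 69.8 to 2016 ± 209.6 CPM, n = 4 per group). Their hypoxia and glycolysis list fell, with Egln3 6.81-fold and Hk2 2.87-fold lower (adjusted p = 1.76e-07, and adjusted p = 0.209 with an estimated correlation), and the macrophage genes Apoe and Pf4 fell 15.3-fold and from 282 to 2.08 CPM. Ifng was at 96.4 CPM in neutrophils of iIL12 tumours with no UMI in iLuc, and their cytotoxic list (adjusted p = 0.0188, and adjusted p = 0.147 with an estimated correlation) had adjusted p = 0.243 after free RNA was subtracted. In regulatory T cells, Foxp3, their master regulator (ENSMUSG00000039521, chromosome X, 7573644 to 7595245), and Il10 did not differ (adjusted p = 0.914 and adjusted p = 0.854). There Ifng rose 80.9-fold, Il12rb2 7.13-fold, Tbx21 2.59-fold, Prf1 8.03-fold and Gzma 112-fold, and Gzmf went from 0.88 ± 1.76 to 255 ± 400.2 CPM. In their cytotoxic list 13 of 15 measured members rose, 13 adjusted over the list alone (adjusted p = 1.48e-25, and adjusted p = 0.00486 with an estimated correlation). Free RNA was 5.64% ± 5.51 in iLuc and 8.12% ± 4.05 in iIL12 of regulatory T cell UMIs. After its subtraction, scaled on macrophage genes, the list had adjusted p = 5.46e-20. Log2 fold changes of Ifng, Il12rb2, Tbx21 and Prf1 were 6.03, 2.85, 1.40 and 2.95, and Gzma and Gzmf had too few UMIs to be tested. RNA of CD8 T or NK cells in the same droplets was not removed and stays open. Mki67 fell 3.79-fold, in a cell cycle list with 9 of 21 members lower (adjusted p = 7.86e-07, and adjusted p = 0.276 with an estimated correlation), and Rad51b and Cd83 fell 7.26-fold and 6.2-fold, the latter not called with free RNA subtracted or with DESeq2 (log2 fold change -2.89 and -2.23). Without iIL12 replicate 2 that of Cd83 was -3.82 against -2.63, and without iLuc replicate 4 that of Gzma 8.86 against 6.81. In B cells Iigp1 and Cxcl10 rose 145-fold and 101-fold, Cul2 and Prim2 fell 3.5-fold and 3.48-fold, and in MHC class I presentation 16 of 18 measured members rose, 18 adjusted over the list alone (adjusted p = 3.31e-19, and adjusted p = 0.0444 with an estimated correlation). The macrophage gene C1qb rose in these cells too, from 42.3 ± 45.6 to 505 ± 611 CPM (adjusted p = 0.00624). Free RNA was 26% ± 4.38 in iLuc and 39.8% ± 14.8 in iIL12 of B cell UMIs, at its upper limit in 2 iIL12 libraries. After its subtraction Cxcl10 and C1qb had too few UMIs to be tested, and Iigp1 had none in iLuc. Fewer B cell genes were called with free RNA subtracted or doublets kept, and 200 without iLuc replicate 1, against 462 in the main fit. In the interferon gamma response 26 of 27 members rose in neutrophils (adjusted p = 2.24e-50, and adjusted p = 0.0331 with an estimated correlation), 18 of 23 in regulatory T cells (adjusted p = 1.32e-18, and adjusted p = 0.0247 with an estimated correlation) and 18 of 19 in B cells (adjusted p = 1.37e-44, and adjusted p = 0.0211 with an estimated correlation), and none fell. In neutrophils 302 rose and 226 fell of 3752 tested genes at 138595 to 578267 UMIs per library, in regulatory T cells 408 rose and 351 fell of 4897 tested at 165857 to 643737, and in B cells 307 rose and 155 fell of 2612 tested at 81393 to 409514. Values did not overlap in 695 (18.5%), 810 (16.5%) and 581 (22.2%) genes, against 2.86% by chance. Named rises and falls had adjusted p of at most 0.00255, 0.00399 and 0.00761. Lists called were 13, 13 and 7, of which 3, 5 and 2 held with an estimated correlation.

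Cells with markers of types that carry no CD45 were compared as well, tumour cells first. Their proliferation genes fell: Mki67 10.5-fold (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), from 178 ± 22.9 to 18.9 ± 21.2 CPM (n = 4 per group, adjusted p = 2.15e-05), and Cdc20 and Aspm 19-fold and 20.9-fold (Aspm at log2 -5.80 without iIL12 replicate 1, against -4.38), with 29 of 30 cell cycle members lower (29 adjusted over the list alone; adjusted p = 3.31e-20, and adjusted p = 0.124 with an estimated correlation). Cd274 rose 28.6-fold. In the interferon gamma response 28 of 28 measured members rose, 28 adjusted over the list alone, with a median log2 fold change of 5.10 (adjusted p = 1.20e-80, and adjusted p = 0.00736 with an estimated correlation). Antigen presentation genes rose, Psmb9 44.7-fold and H2-T22 31.6-fold in class I (adjusted p = 1.50e-65, and adjusted p = 0.00736 with an estimated correlation) and Cd74 39.1-fold in class II (adjusted p = 3.39e-13, and adjusted p = 0.124 with an estimated correlation). Serping1 went from 0.0193 ± 0.0385 to 46.6 ± 39.2 CPM and Apol6 from 0.0649 ± 0.0939 to 67.5 ± 25.8 CPM. The melanocytic and tumour list itself did not differ in these cells (3 and 2 of 8, adjusted p = 0.39). In the cluster with fibroblast markers, whose melanocytic transcripts are given above, Iigp1 rose 143-fold, Ubd at least 98.7-fold from no UMI, and Cxcl9 and Cxcl10 139.9-fold and 101-fold. Without iIL12 replicate 4 the log2 fold changes of Iigp1 and Cxcl9 were 5.92 and 5.81, against 7.16 and 7.13, and without iLuc replicate 3 that of Iigp1 was 8.43. Atp13a2 went from 109 ± 28.5 to 8.47 ± 14.7 CPM, and Pdk1 fell at least 9.78-fold to no UMI. Both falls lost their call without iIL12 replicate 3 (log2 fold change -3.30 for Atp13a2, adjusted p = 0.316 for Pdk1) and without iIL12 replicate 4 (-4.50, and adjusted p = 0.0829), and that of Pdk1 also with free RNA subtracted (adjusted p = 0.0791). In their interferon gamma response 19 of 23 measured members rose, 23 adjusted over the list alone (adjusted p = 7.88e-62, and adjusted p = 0.0104 with an estimated correlation). Free RNA was 24.2% ± 21.6 in iLuc and 9.06% ± 6.17 in iIL12 of this cluster's UMIs. In tumour cells 2632 rose and 2488 fell of 11523 tested genes at 808830 to 14378824 UMIs per library, with 4592 (39.9%, against 2.86% by chance) not overlapping. In the cluster with fibroblast markers 74 rose and 18 fell of 3127 tested, from 4 iLuc and 3 iIL12 libraries at 45249 to 1438427 UMIs, with 377 (12.1%, against 5.71% by chance) not overlapping. Named rises and falls had adjusted p of at most 2.15e-05 in tumour cells and 0.0395 in the cluster with fibroblast markers. Lists called were 16 and 10, of which 3 and 2 held with an estimated correlation.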

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

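The tests chosen only after the result was seen are, for the lower share of dendritic cells, the ratio of cDC2 to cDC1 cells, the fold of cDC2 in other clusterings and the higher UMI minimum, for cytotoxic genes in myeloid cells, the T cell markers and the share of the difference left at each level, and, for interferon genes, the restriction to members measured both times. Of 465 groups of 4 libraries tested, 46 (9.89%) held 1 library far from the other 3, where chance gives about 1 in 20 (5%) for independent values of normal spread. Some of the 46 held a few UMIs in 1 library and 0 CPM in the other 3, which the rule always flags. No excess over chance is therefore shown. Replicate 3 of iLuc was the distant library in 13 of the 46 and replicate 2 of iIL12 in 10. Total UMIs were 130381885 in iIL12 1, against 110368354 to 113718126 in the other 3. B cells were 0.355% of iLuc 3 (others 1.28% to 1.44%), and monocytes 33.7% of iIL12 2 (others 19.3% to 21.2%).

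In CPM, the whole population had Mt3 1.03 in iLuc 3 (others 1.48 to 1.54), Ano3 3.62 in iIL12 1 (others 0.66 to 1.12), Il12rb2 51.4 in iLuc 1 (others 29.1 to 31.2), Tbx21 16.9 in iLuc 1 (others 11.3 to 11.7) and Foxp3 6.56 in iLuc 3 (others 2.32 to 2.84). Macrophages had Majin 34.6 in iIL12 2 (others 14.6 to 17.1), Fcrls 53.7 in iLuc 3 (others 7.78 to 12.4), Gas6 112 in iLuc 3 (others 14 to 30.3), Retnla 6.18 in iIL12 3 (others 0.0459 to 0.319), Igf1 107 in iLuc 3 (others 16.8 to 23), Cxcl10 196 in iLuc 3 (others 343 to 372), Ccl5 799.5 in iIL12 3 (others 314 to 389.6), Mrc1 899 in iLuc 3 (others 341 to 361) and Mrc1 91.9 in iIL12 4 (others 64.6 to 68.4). Monocytes had Hspa1b 18.4 in iIL12 2 (others 4.64 to 6.79) and H2-Q7 437 in iIL12 2 (others 539 to 545). CD8 T cells had Mecom 0.239 in iLuc 2 (others 0), P2rx3 1.4 in iLuc 3 (others 0 to 0.239), Fes 104 in iIL12 1 (others 89.4 to 90.9), Ccl1 0.102 in iIL12 1 (others 0) and Egr1 16 in iLuc 2 (others 20.3 to 21). NK cells had Upk1a 0.473 in iLuc 3 (others 0), Timp3 0.946 in iLuc 3 (others 0), Mecom 6.62 in iLuc 3 (others 0.38 to 0.544), Btbd11 9.05 in iIL12 2 (others 1.25 to 2.3), Hvcn1 0.209 in iIL12 3 (others 0.627 to 0.676), Il12rb1 42.2 in iIL12 2 (others 59.6 to 62.4), Tcf7 1.88 in iIL12 4 (others 4.9 to 5.34), Ccr7 43 in iLuc 2 (others 25.5 to 27.6) and Pkm 741 in iIL12 2 (others 923 to 957). In cDC2 there were St6gal1 29.3 in iLuc 3 (others 17.9 to 18.5), St6gal1 3.82 in iIL12 3 (others 0) and Clec4b1 43.3 in iLuc 1 (others 83.2 to 90.5), and in migratory DC Ceacam15 3.52 in iIL12 2 (others 0). Neutrophils had Pf4 8.32 in iIL12 2 (others 0). Regulatory T cells had Gzmf 3.52 in iLuc 2 (others 0), Gzmf 855 in iIL12 1 (others 33 to 89.8), Gzma 17.4 in iLuc 4 (others 0 to 1.64), Cd83 59.4 in iIL12 2 (others 0 to 6.91), Ifng 31.8 in iLuc 4 (others 3.52 to 8.21) and Il12rb2 17.6 in iLuc 2 (others 46.3 to 49). Tumour cells had Serping1 0.0771 in iLuc 2 (others 0), and the cluster with fibroblast markers Dct 7352 in iLuc 1 (others 4243 to 4581). In iLuc 3 macrophages Fcrls, Gas6, Igf1 and Mrc1 were high together and Cxcl10 was low. The cause was not tested.

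Cell types differed in how they changed. The change of 4862 genes differed between CD8 T and NK cells and that of 302 between macrophages and neutrophils (edgeR interaction). From CD8 T to NK cells the log2 fold change rose by 2.42 for Gzmb, 2.75 for Prf1, 1.98 for Mki67, 2.41 for Il10 and 1.93 for Cxcl9. It differed by -2.37 for Il12rb2, -1.32 for Stat4, -0.85 for Tbx21, -0.83 for Cd274, -1.82 for Cxcl10 and -1.27 for Arg1. From macrophages to neutrophils it differed by -2.10 for Arg1 and -1.68 for Nos2. Adjusted p ran from 4.90e-09 to 0.0497 over these genes, the highest for Cxcl9 between CD8 T and NK cells. With voom, another model of the same counts, Il10 and Cxcl9 between CD8 T and NK cells (adjusted p = 0.154 and 0.676) and Arg1 and Nos2 between macrophages and neutrophils (0.0666 and 0.522) were not called. The interactions were not rerun with other class definitions or with free RNA subtracted.

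The 8 libraries can be split 4 against 4 in 35 ways (7 libraries, 4 against 3, also 35 for fibroblasts). For the number of changed genes 1 of the 35 splits, the real one, gave as many in each fit. That argues against chance but does not exclude it. A share of 1 in 35 is the lowest possible, the fits were not adjusted for one another, and each other split mixed libraries of both groups. The highest other split gave 0 genes in the whole population (8229), macrophages (5795), monocytes (5613), NK (6652), CD8 T (4588), cDC1 (2024), cDC2 (1008), migratory DC (1341), neutrophil (528), regulatory T (759), tumour cells (5120) and the CD8 T and NK difference (4862), real numbers in brackets. It gave 22 against 462 in B cells, 20 against 92 in fibroblasts and 64 against 302 in the macrophage and neutrophil difference. For the number of gene lists called chance is argued against, by a narrow lead, in CD8 T (1 of 35 splits gave as many, real 13, highest other 12), cDC2 (1 of 35, 15, 14) and neutrophil (1 of 35, 13, 11). It is not argued against in the whole population (12 of 35, 12, 14), macrophages (16 of 35, 10, 14), monocytes (4 of 35, 13, 13), NK (6 of 35, 11, 13), cDC1 (10 of 35, 9, 15), migratory DC (9 of 35, 9, 14), regulatory T (2 of 35, 13, 13), tumour cells (4 of 35, 16, 18), B (12 of 35, 7, 8) and fibroblasts (14 of 35, 10, 15), with the 3 numbers in the same order.

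Interferon gamma response genes were higher in CD8 T and NK cells after AAV-iIL12. Free RNA from other cells is argued against as the whole cause: after subtraction the median log2 fold change was 1.38 against 1.57 in CD8 T and 1.05 against 1.09 in NK cells, the lower ratio being 0.881, and 0.963 over the 22 members measured both times. A difference in depth is argued against too, since thinning to 1 total left a lower ratio of 0.775, and 1.0 over members measured both times. A candidate explanation is that the treatment induced the response in these cells, found and tested on the same data and so a hypothesis. The samples are numbered anew within each group, so a run shared by a group could not be tested and stays open.

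Dendritic cells (cDC1, cDC2 and migratory) were a lower share after AAV-iIL12. Dendritic cells left in unnamed clusters with unchanged markers are argued against as the whole cause. Over all kept cells 33 dendritic markers had a median log2 fold change of -1.31, with 23 lower and 5 higher. Unnamed dendritic cells with lowered markers stay open. The log2 fold of the named share was -3.10, and -3.17 to -1.85 in 8 other choices of cells, clusters and names, the smallest with all variable genes. For cDC2 a count under another name or none may be part of the fall: with all variable genes its log2 fold was -1.35 against -4.07, a ratio of 0.331, so how far cDC2 fell stays open. Whether only other cells became more numerous cannot be told apart from a loss, since shares give no number of cells per tumour. That would leave cDC2 per cDC1 cell as it was, but the ratio fell without overlap in only 2 of 4 clusterings: from 1.69 ± 0.378 to 0.50 ± 0.183 in the main one (n = 4 per group, exact permutation p = 0.0286) and from 1.6 ± 0.348 to 0.391 ± 0.153 at resolution 2. With doublets kept it went from 1.6 ± 0.395 to 1.51 ± 0.045 (exact permutation p = 0.914), and with all variable genes it rose from 1.81 ± 0.443 to 3.53 ± 0.194 (exact permutation p = 0.0286). At 1000 UMIs the log2 fold of the dendritic share was -3.08, a ratio of 0.995, so barcodes under 1000 UMIs contributed little to it. Only 147 to 928 kept cells per library lay under that minimum. They were too few for the criterion set to be met, so that criterion decides nothing. A loss of dendritic cells with the treatment and a batch stay open, neither tested.

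Cytotoxic effector genes were higher in monocytes and macrophages after AAV-iIL12. Free RNA from other cells is argued against as the whole cause for the called members at 20 CPM or more in iLuc (2 in monocytes and 4 in macrophages, among them Tnf and Klrk1), since its subtraction left a median of 1.01 and 1.01 of their difference in CPM. For the 13 and 13 called members below that, granzymes, Prf1 and Ifng among them, RNA of T cells, free or in the same droplets, may account for most of the rise: the median left was 0.0622 and 0.0712, but 0.914 for Ccl5 in monocytes. The amount was scaled on CD8 T genes and so removes both, which leaves open which of the 2 it was. The planned ratio of list medians (lower 0.485) decides nothing, since only 9 of 19 and 9 of 20 members were measured both times. For T cells in the same droplets, 6 CD8 T marker genes had a median log2 fold change of 3.48 in monocytes and 1.78 in macrophages, 1.15 and 0.661 times that of the list, so they stay open, as does expression by the myeloid cells, not tested.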

How the results depend on the processing

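The alternatives chosen only after the data were seen are the earlier naming rule, unnamed clusters placed in their best class, named immune cells, free RNA subtracted, monocytes and macrophages summed, the permutation of list means, and libraries left out for lists and interactions. Of 290 share values under an alternative, 247 kept their call, or lack of one in either direction. So did 4531 of 4574 for named genes and 2923 of 3302 for single lists. Of 465 counts of genes or lists, 412 stayed within 1.5 times, among them each list count with 1 library left out. Weaker, stronger and reversed values were 28, 14 and 1 for shares, 19, 22 and 2 for named genes, and 258, 118 and 3 for lists. Where a value below moved or changed its call, the cause was not tested unless one is given.

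Shares are differences in percentage points. With a UMI minimum of 1000 the fibroblast fall was -1.67 (adjusted p = 0.117), no longer called. The neutrophil fall became called at -0.894 there, -0.842 with the ambient test and -0.829 with at most 5% mitochondrial UMIs. With doublets kept CD8 T cells (9.98) and macrophages (-29) became called, the first with a cluster led by myeloid genes among T and NK cells (4.65 without it), the second with a Nos2 cluster left unnamed (-9.86 with it). At resolution 2 macrophages did (-12.9) and NK cells (1.46, adjusted p = 0.0675) did not stay called. With all variable genes macrophages (-18.7) and monocytes (23.4) became called. With unnamed clusters in their best class CD8 T cells (9.54) and monocytes (17.5) did, and monocytes also as a share of myeloid cells (16.8). As a share of T and NK cells NK cells reversed to -8.82 (adjusted p = 0.286) and gamma-delta T cells weakened (-0.912).

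The earlier naming rule left 7 classes just short of the threshold (adjusted p = 0.0531): B -0.815, NK 1.76, cDC1 -3.67, cDC2 -6.91, migratory DC -3.44, pDC -1.1 and tumour -1.27. Among named immune cells 7 did so too (adjusted p = 0.0531, B 0.0825): B -0.857, NK 3.89, cDC1 -4.23, cDC2 -8.27, gamma-delta T -0.121, migratory DC -4.0 and pDC -1.35. In both the smallest p of 70 permutations is 0.0286, so fewer classes at that p raise the adjusted p. Among named immune cells B cells also had a larger permutation p of their own, so the adjustment alone does not account for their lost call. With replicate numbers as a block no p can be below 0.125, and all 9 called shares had adjusted p = 0.17: B -0.815, NK 1.75, cDC1 -3.67, cDC2 -6.91, fibroblast -4.06, gamma-delta T -0.106, migratory DC -3.44, pDC -1.1 and tumour -1.27. The numbers do not pair the samples, so this says nothing about stability. In edgeR on cell counts (log2 fold change) CD8 T (1.99), monocyte (1.11) and mast cells (-5.19) became called, and B (-1.23, adjusted p = 0.103) and gamma-delta T cells (-1.91, adjusted p = 0.14) lost the call. Leaving out 1 library gave these ranges: B -1.06 to -0.702, CD8 T 3.12 to 5.42, NK 1.59 to 2.11, cDC1 -4.13 to -3.22, cDC2 -7.32 to -6.58, migratory DC -3.86 to -2.98, pDC -1.27 to -0.85, gamma-delta T -0.123 to -0.0844, neutrophil -1.0 to -0.635, tumour -1.45 to -1.09. Those that moved over 1.5 times were fibroblast -5.32 to -1.1 (nearest 0 without iLuc replicate 3), macrophage -10.8 to -5.06 (without iLuc replicate 4), mast -0.107 to -0.045 (without iLuc replicate 3) and monocyte 0.783 to 5.59 (2.7 without iLuc replicate 3, lowest without iIL12 replicate 2). Regulatory T cells (-0.339 to 0.132) moved without each library except iLuc replicate 2 and rose without iLuc replicate 3.

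The number of gene lists called depended on how the correlation between genes was treated. Camera's preset and estimated correlation called 12 and 0 in whole population, 7 and 2 in B, 13 and 2 in CD8 T, 11 and 2 in NK, 9 and 3 in cDC1, 15 and 6 in cDC2, 10 and 2 in fibroblast, 10 and 2 in macrophage, 9 and 1 in migratory DC, 13 and 4 in monocyte, 13 and 3 in neutrophil, 13 and 5 in regulatory T, 16 and 3 in tumour. The permutation of list means called 0 in B, cDC1, fibroblast, migratory DC and neutrophil cells. The means of 5, 7, 6, 11 and 8 lists did not overlap there, too few for the smallest p of 0.0286 to pass the adjustment, so this says nothing about stability. It called 13 in macrophages and 16 in monocytes. Fry called 4 in B cells and 4 in fibroblasts, and with free RNA subtracted B cells had 4. With free RNA subtracted the melanocytic list reversed in macrophages (adjusted p = 0.00277), with Dct at 9.37 and Tyrp1 at 8.80 on the log2 scale; iLuc was left with no UMI of either, so these are no measured folds. The cytotoxic list reversed in neutrophils (adjusted p = 0.243). With 1 library left out the cytotoxic list in fibroblasts had adjusted p from 0.00392 to 0.644, the highest without iLuc replicate 1, where it reversed.

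Counts of changed genes in the whole population (6998 to 9223 with 1 library left out), macrophages (4845 to 6387), monocytes (4910 to 6138), NK (6065 to 6645) and cDC1 cells (1394 to 2244) stayed within 1.5 times under each alternative run. In B cells the 462 genes became 293 with the 5% limit, 176 with doublets kept, 97 with free RNA subtracted, 715 with no gene filter and 235 after thinning. In cDC2 the 1008 became 2981 with doublets kept, 3157 with all variable genes, 1668 with unnamed clusters placed and 399 after thinning. In fibroblasts the 92 became 648 with no filter and 29 after thinning. Thinning to the smallest library, which removes counts, also left 2902 in CD8 T, 718 in migratory DC, 323 in regulatory T and 2742 in tumour cells, so depth limits these counts. Limma voom gave 464 genes for the macrophage and neutrophil difference. Leaving out 1 library gave 200 to 616 in B cells (lowest without iLuc replicate 1, with 278 and 301 without iIL12 replicates 2 and 3). In fibroblasts it gave 33 to 240 (highest without iIL12 replicate 1, 45 and 42 without iLuc replicates 2 and 3, 33 and 52 without iIL12 replicates 3 and 4). In neutrophils it gave 343 to 557 (343 and 344 without iIL12 replicates 1 and 4). In regulatory T cells it gave 406 to 1057 (476 without iLuc replicate 3, 432 and 406 without iIL12 replicates 1 and 3). The other ranges were CD8 T 3881 to 4839, cDC2 735 to 963, migratory DC 979 to 1303 and tumour 4282 to 5362. For differences between classes they were CD8 T and NK 4342 to 4745, and macrophage and neutrophil 164 to 363 (199 without iLuc replicate 2, 201 and 164 without iIL12 replicates 1 and 4).

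Among named genes, Stat4 in the whole population became a called fall in 6 settings, from -0.44 with the replicate block to -1.12 in named immune cells. Mki67 became a called rise in named immune cells (0.76) and without iIL12 replicate 2 (0.60). In CD8 T cells Gzmb became a called rise in 7 settings, up to 1.19, and the falls of Gzmd and Gzme lost their call at resolution 2 (-0.40 and -1.08), with all variable genes and with unnamed clusters placed, as did Gzmd with doublets kept (-1.96). The Arg1 fall in macrophages lost it with doublets kept (-0.20) and at resolution 2 (-0.33). With 1 library left out, the fold of a named gene moved by over 2 times in 30 of 1728 values, 7 of them nearer to 0. Some alternatives gave no value. Fibroblasts had too few libraries for expression with the 1000 UMI minimum and the 5% limit, and iIL12 replicate 2 had too few of them to enter any fit. The earlier naming rule named no fibroblast or gamma-delta T cluster, resolution 2 no gamma-delta T or mast cell cluster, and the clustering with doublets kept no mast cell cluster.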
